A study of Mus musculus with 3 samples.

How the data were processed

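Expression was measured in 3 samples of 1 group: mammary cells with high CD49f and high Lgr5 reporter signal, sorted from female embryos at embryonic day 14, each sample a pool of the female embryos of 1 litter. Per the labels' protocols, epidermis and mammary gland were digested with collagenase and hyaluronidase, a sort yielded either 813 or 2000 cells per sample, and cDNA made from their RNA was amplified by whole transcriptome amplification for 25 cycles before labelling with biotin. The labels do not say which sample had which number of cells. The deposited values are log2 expression per probe set, and the submitters' processing notes name RMA and the affy package, without versions or settings. RMA in general corrects the background, normalizes between arrays and summarises probes, which compresses differences of weak probe sets. Replicates 1 and 2 shared a distribution of values and replicate 3 did not. Without the settings, it is not known whether the 3 arrays were normalized together. The probe set names are those of an array type with perfect match probes alone.

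The table held 45141 probe sets. Of these, 104 were controls of the manufacturer. A table of the platform annotation paired 28898 probe sets with 1 gene symbol and 551 with several, and 15588 had no listed gene. Probe sets with several genes or none were left out of the comparisons. A gene measured by more than 1 probe set (7180 of 17097 genes) was represented by the probe set with the highest mean over the arrays. Some members of the preset lists were not analysed here, and the counts for each list cover its measured members. Probe sets of 1 gene lay on both sides of the threshold for 24 of 157 genes named by rule: Cldn1, Cldn3, Csn2, Dsc3, Edar, Fgf1, Fgf4, Firre, Hnf4a, Hoxa3, Isl1, Itga4, Itgb1, Krt6a, Msx2, Myef2, Myh11, Oxtr, Septin7, Shroom3, Sry, Top2a, Trp63 and Wnt6.

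With 1 group and no control samples, each gene was tested against a background measured on the same arrays. The background set was 74 olfactory and vomeronasal receptor genes, and the threshold of an array was their 95th percentile. The threshold was subtracted from the log2 value of each gene, and the mean over the 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (intercept fit, empirical Bayes with a trend on the mean, one-sided p, Benjamini-Hochberg over 17097 genes). A gene with an adjusted p under 0.05 was called above background. The p-values rest on the spread over the 3 arrays, with variances moderated over all genes, and leave out the uncertainty of the threshold. Each litter was on 1 array, so differences between litters cannot be told from those of batch, number of cells or processing. Levels of different probe sets were not ranked against each other. No count depth exists for arrays, and their number limited the precision.

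Gene lists for mammary lineages, pathways, other cell types and gene families were fixed before the data were examined, as were the test, the named-gene rule and most of the alternative settings. Of these, 29 lists were tested with Fisher's exact test, two-sided, on members above and not above background against all other named genes outside the background sets, with Benjamini-Hochberg adjustment over the 29. Lists for dissociation stress, housekeeping, Y-linked and X-inactivation genes were counted and not tested. Basal against luminal genes, and mammary genes (basal, luminal and bud) against genes of other cell types, were compared by Fisher's exact test without shared members. Genes of a list are not independent replicates, so these tests describe these arrays. Odds ratios were computed with 0.5 added to each cell.

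Differences between litters were described and not tested, since each litter was measured once. For each list with at least 3 genes above background, the median of an array's values minus the mean of the other 2 arrays was set against 10000 random lists of the same size drawn from genes above background in 20 bins of mean level, and called outside beyond the central 99.8%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used besides R.

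Genes were named by a rule. It took Lgr5, Itga6, Trp63, Krt5, Krt14, Krt8, Krt18 and Krt19 always. In list order, it took the first 6 members above background and the first 3 others of the basal, luminal and bud lists, and the first 3 and the first 2 others of each other list. It added the 12 genes above background with the largest range over the arrays, and per array the 4 furthest above and the 4 furthest below the mean of the other arrays. Genes named outside the rule were chosen after their values were seen. Jag1, Dst and Vim were named as list overlap, and Fgf11, Fgf12, Fgf13 and Fgf14 for their products. The others were Olfr544, Prm1, Gad2, Dcn, Twist2 and the members of the lists added later.

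The steps were tested on simulated data. For the test of genes above background (17097 genes), 54%, 84%, 96% and 98% of 50 genes planted 0.25, 0.5, 1 and 2 log2 units above the threshold were recovered, and 13 of 5942 genes with means under the threshold (0.219%) were called. For list shifts (9426 genes), 40 of 40 lists of 12 genes raised by 0.6 on replicate 2 were outside the central range, and 0 of 120 unchanged pairs were. The unchanged lists were random genes, so they do not cover lists whose genes vary together. For the list test, 6 of 200 random lists of 20 genes (3%) had a p under 0.05, and 200 of 200 lists with 18 of 20 members above background did.

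Alternative settings fixed at that point were the 99th and the 90th percentile of the background set, 44 measured genes restricted to unrelated tissues as background set, the mean of a gene's probe sets, leaving out probe sets marked as able to cross-hybridise, centring each array on its median, requiring every array above its own threshold without a model, and leaving out each replicate. For list shifts they were the mean over members, all members, the mean of a gene's probe sets and a loess correction (span 0.3) for the trend with level. Chosen after seeing the data were replicates 1 and 2 averaged as 1 sample, the brightest antigenomic control probe set (log2 7.36, 7.31 and 7.48) as threshold, and joint quantile normalization of the 3 arrays. Antigenomic control probe sets match no transcript of the mouse and measure nonspecific hybridisation.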

Results

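RNA of embryonic mouse mammary cells was profiled on 3 Affymetrix arrays. The cells were sorted by flow cytometry from female embryos at embryonic day 14 for high surface CD49f, the integrin alpha 6 chain that marks basal epithelium, and for high green fluorescence in mice that carry the fluorescent protein at the Lgr5 locus. Lgr5 encodes a receptor of the R-spondins and is a target gene of Wnt signalling. Each array held the pooled female embryos of 1 litter, so the 3 arrays were biological replicates of 1 group, and no second group was compared. The series title places the cells in a study of p63 and the loss of multipotency in the mammary gland. The comparisons below therefore asked which lineage programmes gave a signal above background in these cells, whether basal genes were detected more often than luminal genes, whether other cell types left a signal, and how the litters differed. No coordinates are given, because no genome build was named for the arrays.

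Of 17097 genes measured by at least 1 probe set of a single gene, 9426 (55.1%) were above background, and 9737 had an unadjusted p under 0.05. The count depended on the threshold, and was 5446 with tissue-restricted genes as background and 5399 with the brightest antigenomic control. Background was the 95th percentile of 74 chemosensory receptor genes on each array, which lay at log2 values of 6.14, 6.17 and 5.99 on replicates 1, 2 and 3. The arrays had median log2 values of 6.25, 6.25 and 6.52, and 10647, 10564 and 11484 genes lay above the threshold of their own array. Among genes above background the median SD over the litters was 0.26. One receptor gene of the background set itself, Olfr544, was above background, and so were 11 of 44 genes restricted to unrelated tissues, such as Prm1 of sperm (8.02 ± 0.08, SD, n = 3) and Gad2 of inhibitory neurons (7.66 ± 0.46). When the 95th percentile of these same tissue-restricted genes set the threshold, 1 of them was above background. Such a low number is largely fixed by that choice, as it is for the receptor genes under their own threshold. With 3 arrays, their number limited the precision.

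Both genes used for the sort gave a clear signal. Lgr5 had a log2 value of 10.27 ± 0.44 (SD, n = 3), which was 4.17 above the threshold (adjusted p = 6.34e-05). Itga6, which encodes CD49f, stood at 10.37 ± 0.40, 4.27 above the threshold (adjusted p = 5.17e-05). Trp63, which encodes the basal epithelial transcription factor p63, stood at 10.53 ± 0.39 (adjusted p = 4.33e-05). The 4 probe sets of Trp63 differed, and the lowest lay below the threshold (-1.45). The 2 sort genes were too few for a list test (exact Fisher adjusted p = 0.691).

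Basal epithelial genes were detected almost throughout. Of 19 measured mammary basal genes, 17 were above background, over all genes tested and also adjusted over the list alone, against 55.4% of the other genes (exact Fisher adjusted p = 0.0157). Krt5 and Krt14, the keratin pair of basal cells, had log2 values of 12.15 ± 0.16 and 11.38 ± 0.25 (SD, n = 3). The hemidesmosome integrin gene Itgb4 stood at 9.79 ± 0.19, its relative Itgb1 at 10.76 ± 0.06, the P-cadherin gene Cdh3 at 9.52 ± 0.07 and the transcription factor gene Snai2 at 7.61 ± 0.16. The 2 members not above background were the Notch ligand gene Dll1 (6.29 ± 0.43) and Procr (5.15 ± 0.05), which encodes the endothelial protein C receptor. All 15 measured members of a list of p63 target genes were above background (15 adjusted over the list alone; exact Fisher adjusted p = 0.00361). They included Perp, a desmosome gene (10.28 ± 0.33), and the fibroblast growth factor receptor genes Fgfr2 (11.73 ± 0.34) and Fgfr3 (7.44 ± 0.23). Of the 15, 6 (Itgb4, Cdh3, Krt5, Krt14, Jag1 and Dst) also stood on the basal list. Basal and p63 target lists passed their threshold in each of the 13 alternative settings.

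Luminal keratins were detected in the same pools as the basal ones. Each array measured RNA of pooled cells, so expression of both in 1 cell cannot be told from a mixture of cells. Krt8 and Krt18, the keratin pair of simple and luminal epithelium, had log2 values of 10.07 ± 0.33 and 8.89 ± 0.51 (SD, n = 3), and Krt19 stood at 7.43 ± 0.20. All 3 were above background on each array, with adjusted p of 4.80e-05, 0.000291 and 0.000486. The epithelial surface genes Epcam (10.31 ± 0.40) and Cd24a (11.73 ± 0.25) were above background as well, as was the tight junction gene Cldn3 (7.13 ± 0.27), which fell under the threshold set by tissue-restricted genes. The 8 luminal genes not above background included the transcription factor genes Foxa1 (4.74 ± 0.39) and Elf5 (5.93 ± 0.49) and the keratin gene Krt7 (6.04 ± 0.15). In all, 20 of 28 measured luminal genes were above background (20 adjusted over the list alone), a share that did not pass the test against other genes (exact Fisher adjusted p = 0.244). The basal list had 89.5% of its members above background and the luminal list 71.4%, a log2 odds ratio of 1.54 that was not significant (two-sided exact Fisher p = 0.168). This comparison stayed without a call in all 13 alternatives, with p between 0.0640 and 0.199.

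**Figure D1:**
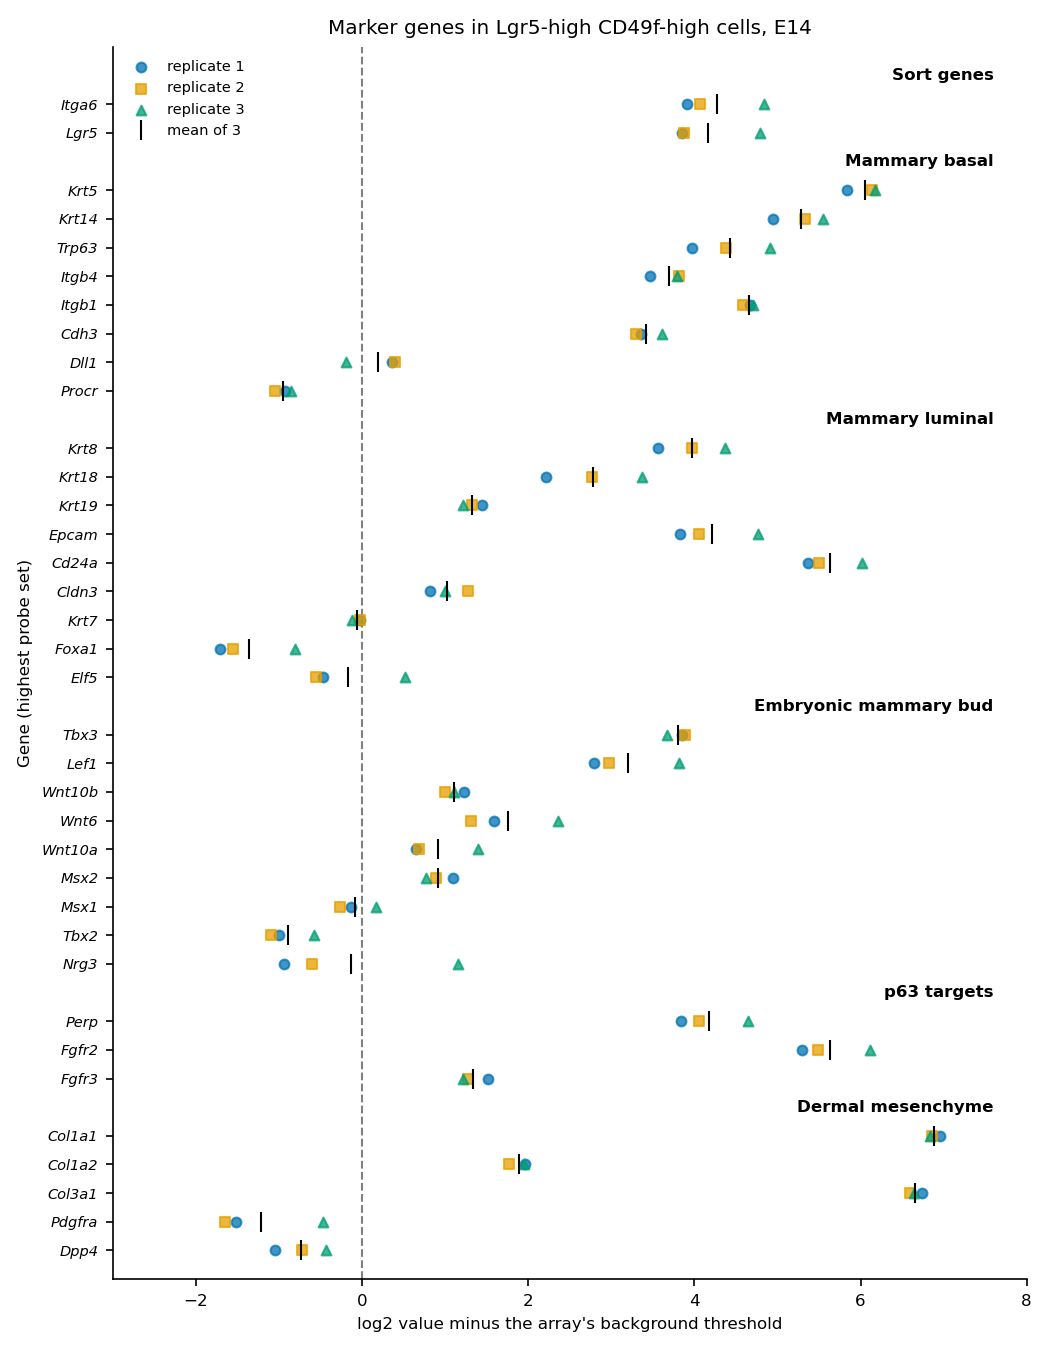
Log2 value of each named marker gene minus the background threshold of its array (x axis), for replicates 1, 2 and 3 (points) and their mean (black tick), by gene list. Krt5 lay 6.05 above the threshold and Krt8 3.97 above it, whereas Foxa1 and Procr lay below it on all arrays.

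Milk protein genes did not pass the test against other genes. Of 9 measured members, 4 were above background (exact Fisher adjusted p = 0.691), and Csn1s1 (4.18 ± 0.07) and Csn1s2a (5.97 ± 0.61, SD, n = 3) were not. Csn2, the beta-casein gene, had a log2 value of 9.43 on replicate 3 against 7.51 and 7.55 on the others. Its probe sets disagreed, and their mean was below the threshold. Wap (6.73 ± 0.51) and Ltf (6.60 ± 0.09) were above the receptor threshold and below that of the tissue-restricted genes. Of the 8 measured genes of myoepithelial contraction, 4 were above background (exact Fisher adjusted p = 1). Acta2, the smooth muscle actin gene, stood at 9.56 ± 0.82 and Mylk, the myosin light chain kinase gene, at 8.52 ± 0.74. Myh11 stood at 7.24 ± 0.57 and was under the tissue-restricted threshold, and Cnn1 (5.59 ± 0.43) and the oxytocin receptor gene Oxtr (6.32 ± 0.16) were not above background.

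Genes of the embryonic mammary bud were above background in 15 of 20 cases (15 adjusted over the list alone), a share that did not pass the test against other genes (exact Fisher adjusted p = 0.234). Tbx3, a transcription factor gene needed for mammary placode formation, had a log2 value of 9.90 ± 0.21 (SD, n = 3), and Lef1, a transcription factor gene of the Wnt pathway, stood at 9.30 ± 0.46. The Wnt ligand genes Wnt6 (7.85 ± 0.44), Wnt10b (7.21 ± 0.14) and Wnt10a (7.01 ± 0.33) and the homeobox gene Msx2 (7.02 ± 0.24) were above background, and all of these but Wnt6 were under the tissue-restricted threshold. Msx1 (6.02 ± 0.12) and Tbx2 (5.21 ± 0.17) were not above background. Nrg3, which encodes a ligand that takes part in placode specification, had 7.14 on replicate 3 and 5.20 and 5.57 on replicates 1 and 2, and was not above background by the test.

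Canonical Wnt response genes were above background without exception, 15 of 15 (15 adjusted over the list alone; exact Fisher adjusted p = 0.00361). The 15 included Lgr5, whose reporter the cells were sorted for. Axin2, a feedback inhibitor gene induced by Wnt signalling, stood at 8.89 ± 0.46 (SD, n = 3), and Sp5 stood at 6.70 ± 0.39, under the tissue-restricted threshold. This list lost its call with the 99th percentile as threshold (adjusted p = 0.0641), with tissue-restricted genes as background (0.0974) and with the brightest antigenomic control as threshold (0.0932). Of 19 Wnt ligand genes 10 were above background (exact Fisher adjusted p = 0.897), led in symbol order by Wnt2b (7.49 ± 0.60), Wnt3 (6.91 ± 0.65, under the tissue-restricted threshold) and Wnt4 (9.36 ± 0.21), while Wnt1 (4.87 ± 0.05) and Wnt2 (5.84 ± 0.23) were not. Of 10 Frizzled receptor genes 6 were above background (exact Fisher adjusted p = 1), including Fzd1 (8.84 ± 0.37), Fzd2 (10.54 ± 0.17) and Fzd3 (9.50 ± 0.19) and not Fzd4 (4.63 ± 0.23) or Fzd5 (5.88 ± 0.21). The Notch pathway had 10 of 16 members above background (exact Fisher adjusted p = 0.754). The receptor genes Notch1 (11.50 ± 0.11), Notch2 (10.16 ± 0.26) and Notch3 (8.40, 8.55 and 10.04 on replicates 1, 2 and 3) were above background and Notch4 (5.04 ± 0.07) was not.

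Hox and Fgf families did not pass the test against other genes. Of 34 Hox genes 16 were above background (exact Fisher adjusted p = 0.563), such as Hoxa3 (8.27 ± 0.67), Hoxa9 (8.06 ± 0.45) and Hoxa7 (7.12 ± 0.05, SD, n = 3, under the tissue-restricted threshold), whereas Hoxa2 (4.80 ± 0.16) and Hoxa4 (4.88 ± 0.22) were not. Of 22 genes with an Fgf symbol 8 were above background (7 adjusted over the list alone, exact Fisher adjusted p = 0.192). The 22 included Fgf11, Fgf12, Fgf13 and Fgf14, whose products are not secreted ligands. Fgf1 (6.70 ± 0.05), Fgf4 (6.56 ± 0.10) and Fgf7 (6.53 ± 0.29) were among the 8 but under the tissue-restricted threshold, and Fgf2 (5.56 ± 0.25) and Fgf3 (6.30 ± 0.09) were not above background. The lower share of this Fgf list passed the test in 6 of the 13 alternatives, with exact Fisher adjusted p from 0.00215 to 0.0266 in those.

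Cell cycle genes were detected throughout. All 13 measured proliferation genes were above background (13 adjusted over the list alone; exact Fisher adjusted p = 0.00902). Mki67, the gene of the Ki-67 antigen, stood at 9.82 ± 0.17 (SD, n = 3), the cyclin A2 gene Ccna2 at 10.79 ± 0.25 and the topoisomerase gene Top2a at 8.01 ± 0.14. Top2a fell under the threshold without probe sets marked as cross-hybridising. The list lost its call with the mean of a gene's probe sets (adjusted p = 0.109) and without cross-hybridising probe sets (0.0612).

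Genes of epithelial to mesenchymal transition and of epithelial junctions were both detected. All 9 transition genes were above background (9 adjusted over the list alone; exact Fisher adjusted p = 0.0324), including the transcription factor genes Twist1 (9.80 ± 0.17, SD, n = 3), Snai2 (7.61 ± 0.16) and Snai1 (7.20 ± 0.27, under the tissue-restricted threshold). This call was lost in 4 of the 13 alternatives, with exact Fisher adjusted p between 0.0820 and 0.155 in those. Snai2 and Vim also stood on the basal list, so the 2 lists are not independent. Of 10 junction genes 9 were above background (10 adjusted over the list alone; exact Fisher adjusted p = 0.133). The E-cadherin gene Cdh1 had log2 values of 7.02, 7.62 and 8.36 on replicates 1, 2 and 3, and Tjp1, a tight junction scaffold gene, had 6.83, 7.11 and 8.41. Cldn1 (6.86 ± 0.84) was the junction gene not above background. The junction list passed the threshold without replicate 1, 2 or 3 (adjusted p = 0.0122, 0.0117 and 0.0343) and in 2 other alternatives. On replicate 1, junction genes were lower and transition genes higher than on the other arrays, as given with the litter comparison.

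The families of epithelial structural genes were detected in part. Of 41 keratin genes 14 were above background, below the share of other genes (exact Fisher adjusted p = 0.0324). Krt1 (6.66 ± 0.34) and Krt6a (6.48 ± 0.04, SD, n = 3) were among the 14 but under the tissue-restricted threshold, and Krt2 (4.09 ± 0.32) was not above background. The keratin call was lost in 4 of the 13 alternatives, with adjusted p between 0.0510 and 0.188 in those. Of 23 integrin genes 12 were above background (11 adjusted over the list alone; exact Fisher adjusted p = 0.897), including Itga3 (8.77 ± 0.18), Itga4 (7.86 ± 0.42) and Itga2b (7.09 ± 0.43, under the tissue-restricted threshold) and not Itga1 (5.37 ± 0.03) or Itga2 (6.45 ± 0.12). Of 20 claudin genes 9 were above background (8 adjusted over the list alone; exact Fisher adjusted p = 0.563), among them Cldn4 (9.68 ± 0.44) and Cldn6 (10.57 ± 0.56) and not Cldn2 (6.06 ± 0.20).

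**Figure D2:**
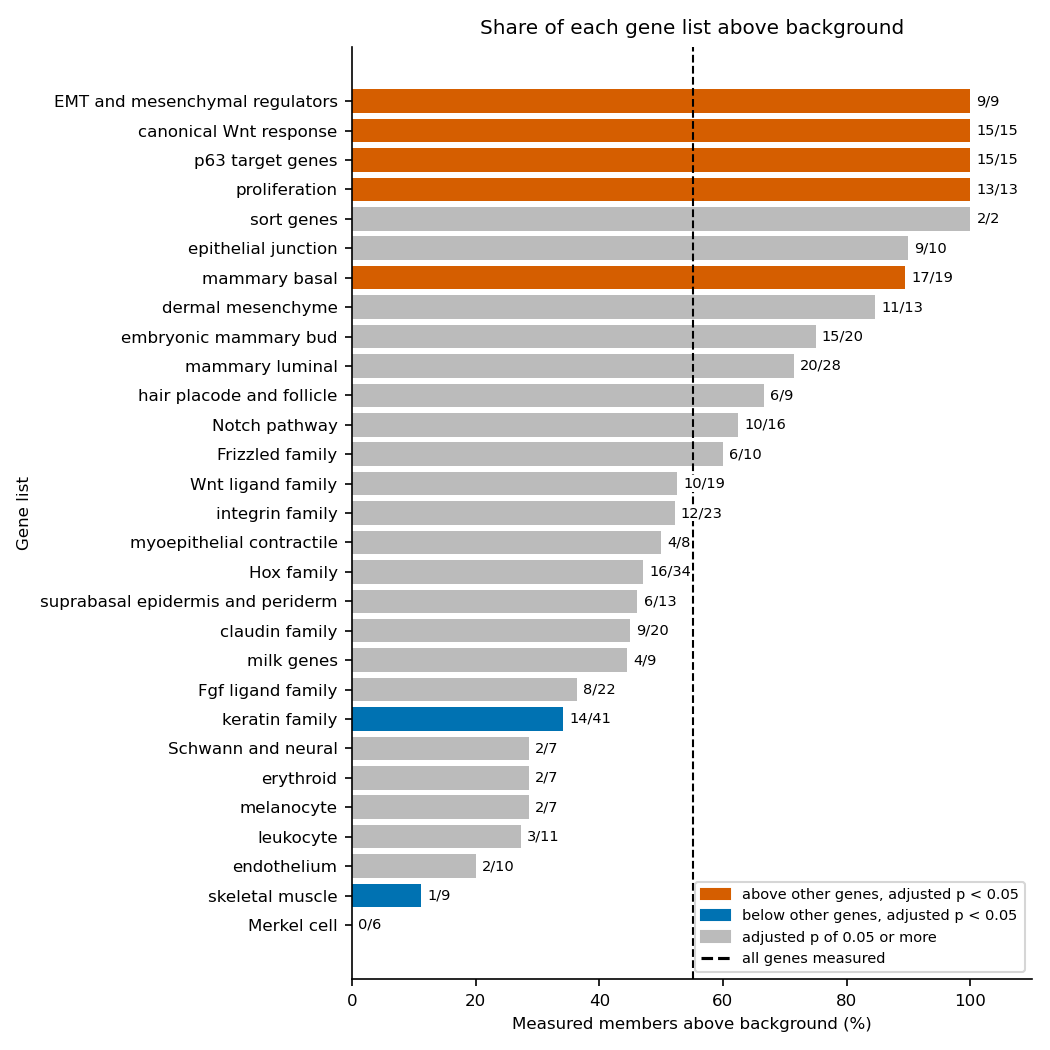
Share of the measured members of each preset gene list above background (bars, in %), with the number above background and the number measured beside each bar. Orange and blue bars passed Fisher's exact test against other genes after adjustment, and the dashed line marks the 55.1% of all measured genes above background. The p63 target and Wnt response lists had 15 of 15 members above background and the Merkel cell list 0 of 6.

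Markers of other cell types of embryonic skin differed in their share above background. It was largest for dermal mesenchyme (11 of 13), hair placode and follicle (6 of 9) and suprabasal epidermis and periderm (6 of 13). In the remaining lists it was at most 28.6%. Only the Merkel cell and skeletal muscle lists fell below the share of other genes by the test. Genes of the mammary basal, luminal and bud lists were above background in 48 of 63 cases (76.2%), against 31 of 87 genes of other cell types (35.6%), with 4 genes on both sides left out. This was a log2 odds ratio of 2.49 (two-sided exact Fisher p = 1.12e-06), and the difference passed in each of the 13 alternatives. No list covered basal epidermis, which was digested along with the mammary gland. The comparison therefore cannot tell basal cells of the 2 tissues apart. No Merkel cell gene was above background (0 of 6; exact Fisher adjusted p = 0.0324), for example Atoh1 (5.20 ± 0.26, SD, n = 3) and Isl1 (6.12 ± 0.22). Of 9 skeletal muscle genes 1 was above background, Myod1 (7.07 ± 0.25), which was under the tissue-restricted threshold, and Myog (5.97 ± 0.15) and Myf5 (3.95 ± 0.13) were not (exact Fisher adjusted p = 0.0485). The Merkel cell call was lost in 7 of the 13 alternatives (adjusted p between 0.0973 and 0.857) and the muscle call in 8 (0.0892 to 0.391). Endothelial genes reached 2 of 10 (exact Fisher adjusted p = 0.0913, and 0.0237 without cross-hybridising probe sets). These were Pecam1 (8.12, 8.30 and 6.47 on replicates 1, 2 and 3) and Egfl7 (7.29 ± 0.40, under the tissue-restricted threshold), while Cdh5 (5.81 ± 0.27) and Kdr (6.35 ± 0.35) were not above background. Leukocyte genes reached 3 of 11 (2 adjusted over the list alone; exact Fisher adjusted p = 0.175), namely Cd68 (8.83 ± 0.26), Csf1r (6.47 ± 0.14) and Fcer1g (7.29 ± 0.45), the last 2 under the tissue-restricted threshold. Ptprc, the pan-leukocyte CD45 gene, was at 4.03 ± 0.20.

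Erythroid, melanocyte and Schwann or neural lists each had 2 of 7 genes above background (exact Fisher adjusted p = 0.409 for each). The erythroid pair was Klf1 (8.15 ± 0.81, SD, n = 3) and Epor (6.76 ± 0.30), the second under the tissue-restricted threshold, and the embryonic globin genes Hbb-y (5.42 ± 0.19) and Hba-x (5.48 ± 0.01) were not above background. Sox10 (8.02 ± 0.22) and Pmel (7.33 ± 0.26) were the melanocyte pair, of which Pmel was below the brightest antigenomic control, and Dct (6.36 ± 0.58) and Tyr (5.16 ± 0.10) were not above background. Erbb3 (9.12 ± 0.43), also a bud gene, and Tubb3 (7.05 ± 0.51, under the tissue-restricted threshold) were the neural pair, and S100b (5.53 ± 0.27) and Foxd3 (5.12 ± 0.36) were not above background. Suprabasal epidermis and periderm genes reached 6 of 13 (exact Fisher adjusted p = 0.734). Krt10, a keratin gene of differentiating epidermis, varied from 6.94 on replicate 1 to 7.70 on replicate 2 and 9.18 on replicate 3. Krt4 stood at 8.96, 8.26 and 5.50 and was not above background by the test, and neither was Krtdap (5.87 ± 0.28). Hair placode and follicle genes reached 6 of 9 (exact Fisher adjusted p = 0.858), with Dkk4 (8.19 ± 0.12), Edar (8.21 ± 1.00) and Shh (6.76 ± 0.12, under the tissue-restricted threshold) above background and Lhx2 (4.67 ± 0.13) and Sox2 (4.05 ± 0.39) not.

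Dermal mesenchyme genes were detected in 11 of 13 cases (11 adjusted over the list alone), with an exact Fisher p of 0.0476 and an adjusted p of 0.133. The fibrillar collagen genes Col1a1 and Col3a1 had log2 values of 12.99 ± 0.15 and 12.76 ± 0.13 (SD, n = 3), and Col1a2 stood at 7.99 ± 0.09. Pdgfra (4.89 ± 0.55), the receptor gene of mesenchymal cells, and Dpp4 (5.37 ± 0.24) were not above background. Under 3 stricter thresholds the list passed: the 99th percentile (adjusted p = 0.0429), tissue-restricted genes (0.00104) and the brightest antigenomic control (0.000948). The median of the mesenchyme genes above background differed from that of the junction genes between arrays. The difference of the medians was -0.32 for replicate 2 minus replicate 1 and -1.08 for replicate 3 minus the mean of the others (log2). No p is given, since each litter was measured once.

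Genes of dissociation and stress, counted as a quality check, were all above background (13 of 13). The immediate early genes Fos, Fosb and Jun, which are induced within minutes of handling, had log2 values of 11.74 ± 0.46, 12.47 ± 0.08 and 11.35 ± 0.24 (SD, n = 3). All 9 housekeeping genes were above background, including Actb (13.35 ± 0.09), Gapdh (12.88 ± 0.15) and Ppia (11.93 ± 0.08). Xist, transcribed from the inactive X chromosome of female cells, stood at 11.33 ± 0.54. Of 6 Y-linked genes, Eif2s3y (4.32 ± 0.03) and Kdm5d (5.75 ± 0.01) and 3 others were not above background. Sry was above it, at 8.09 ± 0.04, but its probe sets disagreed and it lay below the threshold (-0.28) without probe sets marked as cross-hybridising.

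Litters were not equally alike. Replicates 1 and 2 had a Pearson correlation of 0.994 over all probe sets (Spearman 0.994), against 0.942 and 0.944 for replicate 3 with replicates 1 and 2 (Spearman 0.933 and 0.935). These correlations are across probe sets, which are not independent replicates. Of the genes above background, 19 (0.20%) differed by more than 1 log2 unit between replicates 1 and 2, against 1097 (11.6%) between 1 and 3 and 1046 (11.1%) between 2 and 3. Over the 3 litters, 1318 genes (14.0%) had a range over 1, and in 1256 of them replicate 3 was the odd array, the higher in 1063 and the lower in 193. Sorted values of replicates 1 and 2 differed by at most 0.06, whereas those of replicate 3 differed from both by up to 0.45. Replicate 3 thus had another distribution of values. Without replicate 3 the number of genes with a range over 1 was 19.

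Genes with the widest ranges were mostly higher on replicate 3. Lmo7, which encodes a protein of actin and cell junctions, had log2 values of 6.40, 8.01 and 9.58 on replicates 1, 2 and 3. The sialyltransferase gene St8sia4 had 6.60, 7.57 and 9.65. Further genes of this kind were Myef2, Septin7, Tent4b, Ssr4, Tbc1d14, Fzd6, Shroom3, Tfap2b and Firre, which lay between 2.20 and 2.68 above the mean of the other arrays on replicate 3. Myef2 fell below the threshold without probe sets marked as cross-hybridising. Nfatc1, a transcription factor gene active in hair follicle stem cells, was lower on replicate 3 (7.12 against 9.59 and 9.44), as were Zfp469 and Mast1, by -2.18 and -2.15. The hepatocyte factor gene Hnf4a had 7.91 and 7.89 on replicates 1 and 2 and was not above the threshold on replicate 3. Hnf4a and the desmocollin gene Dsc3 lay under the tissue-restricted threshold. Lsp1, a leukocyte gene, had 10.69, 9.86 and 8.70 on replicates 1, 2 and 3. On replicate 2, the mast cell protease gene Cma1 (8.96 against 7.54 and 7.19), the activin antagonist gene Fst (10.24 against 8.81 and 8.68), Dsc3 and Arid5a were higher, and Acta2 was lower (8.61 against 10.08 and 9.98). No test was made, since each litter was measured once.

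**Figure D3:**
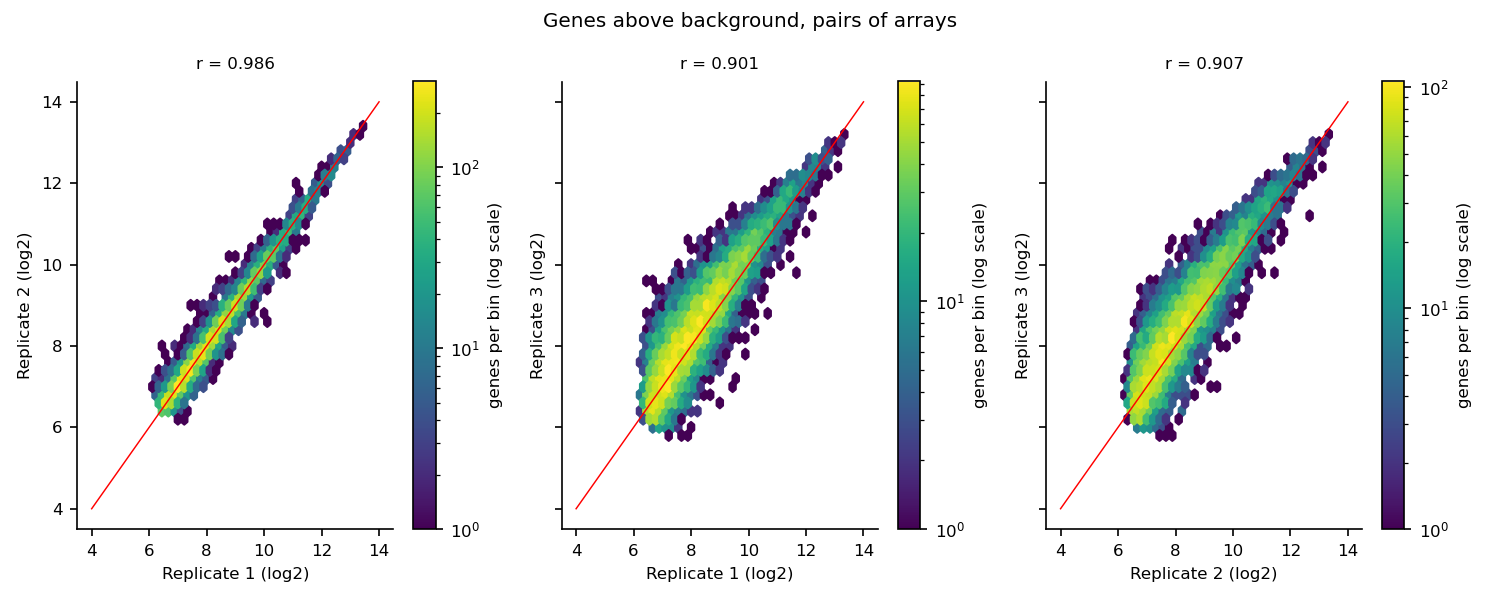
Log2 values of the 9426 genes above background on pairs of arrays (x and y axes), with colour for the number of genes per hexagon on a log scale, Pearson's r above each panel and a red line of equality. Replicates 1 and 2 lay along the line (r = 0.986), and replicate 3 scattered around it against replicate 1 (0.901) and replicate 2 (0.907).

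Whole gene lists also shifted between litters. Over 24 lists with at least 3 genes above background, 8 of 72 list and array pairs lay outside the central range. It was the central 99.8% of 10000 random lists matched on level, where 0.144 pairs would lie outside. Genes of a real list can vary together and the 3 arrays depend on each other, so that number does not exclude chance. Shifts are given relative to the median of those random lists, because the median gene above background differed from the mean of the other arrays by 0.24 on replicate 3 and by -0.11 and -0.13 on replicates 1 and 2. On replicate 1, the 16 Hox genes above background had a relative shift of 0.53, and all 16 lay above the median of the random lists. The transition genes were higher there by 0.39 (8 of 9 genes above that median), and the epithelial junction genes (-0.45) and the stress genes (-0.44) were lower. On replicate 2, the mammary basal genes were higher by 0.30 (13 of 17), the claudin genes by 0.38 and the stress genes by 0.29 (11 of 13), and the myoepithelial contraction genes were lower (-0.50). The shifted stress genes thus stood beside the shifted junction genes on replicate 1 and beside the shifted basal genes on replicate 2.

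Dermal mesenchyme genes (0.29 on replicate 1, -0.49 on replicate 3), bud genes (0.45 on replicate 3) and p63 target genes (0.20 on replicate 2) stayed inside the central range. That holds against the mean of the other 2 arrays. In replicate 2 minus replicate 1 alone, 6 of 24 lists lay outside the range. They were the p63 target (0.29), luminal (0.17), basal (0.16), stress (0.45), contraction (-0.38) and Hox genes (-0.36). Against the mean of the other arrays, no pair of replicate 3 lay outside the central range. Its range was wider, with an SD of gene shifts of 0.58 against 0.34 and 0.32 on replicates 1 and 2. Shifts there reached 0.59 for junction, -0.60 for claudin and -0.50 for Hox and transition genes. They also enter the shifts of replicates 1 and 2 through the mean. In replicate 2 minus replicate 1, claudin (0.09), transition (-0.16) and junction genes (0.21) lay inside the range. The number of pairs outside was 0 without replicate 1 and ranged up to 12 with another array left out. Each of the 8 shifts lay inside the range in at least 1 comparison with a single other array. The basal shift lay inside the range with the mean over members (0.17), the mean of a gene's probe sets (0.21) and joint quantile normalization (0.22). So did the contraction shift with all members (-0.18), the mean of a gene's probe sets (-0.16) and joint quantile normalization (-0.50), the claudin shift with all members (0.11) and the shift of transition genes with the mean of a gene's probe sets (0.33). The Hox shift was 0.17 with all members and stayed outside.

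**Figure D4:**
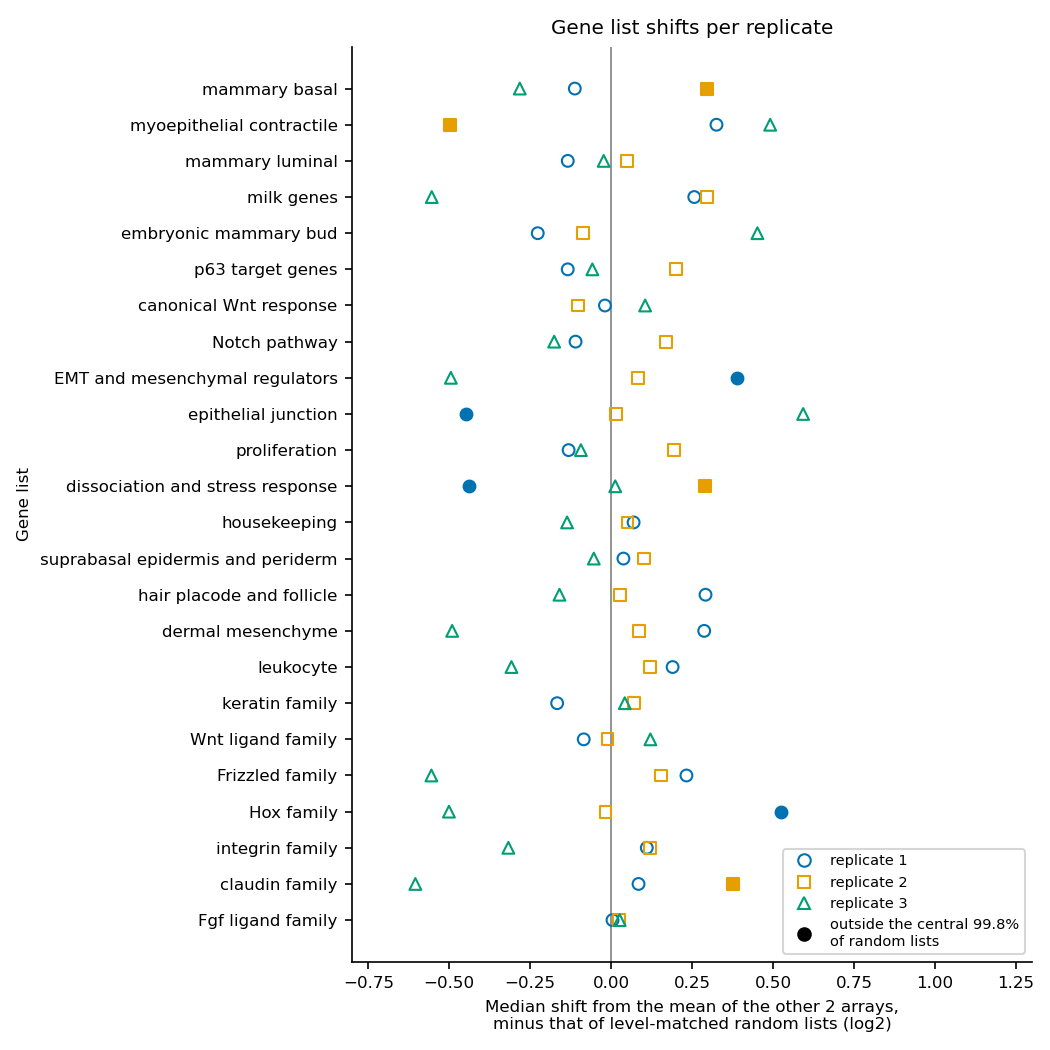
Median shift of each gene list on each array from the mean of the other 2 arrays, minus that of random lists matched on level (x axis, log2), for genes above background of the 24 lists (y axis). Filled symbols lie outside the central 99.8% of random lists, such as the Hox genes on replicate 1 (0.53) and the contraction genes on replicate 2 (-0.50).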

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

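The test against background was fixed before the data were examined, and its use on probe sets outside the comparisons was chosen after seeing the data. Samples far from the others were not tested for, because the group had 3 arrays. Of 16139 probe sets that the platform annotation paired with several genes or with none, 5327 (33.0%) were above background by the same test. They were singled out because they lie outside every comparison of the results. Their transcripts were not identified, and no explanation was tested.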

How the results depend on the processing

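Test, gene lists and all but 3 of the alternative settings were fixed before the data were examined. Averaging replicates 1 and 2, the antigenomic threshold and joint quantile normalization were chosen after seeing the data. Basal against luminal genes stayed without a call in all 13 alternatives (log2 odds ratio 1.54 to 2.35, exact Fisher p from 0.0640 to 0.199), and mammary against other cells passed in all 13 (2.00 to 2.86). No paired analysis was possible because the series has 1 group. Centring each array on its median left the calls above background as they were, by construction, and gave 1082 genes with a range over 1.

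The number of genes above background fell from 9426 to 5446 with tissue-restricted genes as background and to 5399 with the brightest antigenomic control as threshold, both higher thresholds. It was 8169 to 10543 in the other alternatives, and 9056 to 10007 with a replicate left out. Of the 29 lists, 8 passed in the main setting, 4 with the 90th percentile, 5 with tissue-restricted genes, 3 with the mean of a gene's probe sets and 5 with the antigenomic threshold, for causes that were not tested. Without a replicate, 8 to 10 lists passed. Over all alternatives, single lists lost a call 28 times and gained one 15 times, and none changed direction past the threshold. Genes with a range over 1 numbered 1318, or 2287 over all named genes in place of those above background, a wider set. Leaving out 1 replicate gave 19 to 1097, the lowest without replicate 3. Pairs of a list and an array outside the central range numbered 8, and 0 to 12 with 1 array left out, where the remaining 2 arrays mirror each other. The cause was not tested.

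Signal over background limited single genes. Of gene results over all settings, 1808 kept the call they had, 109 lost the call in the same direction, 36 gained it and 62 had a mean under the alternative threshold. Values that follow are means over the arrays minus the alternative threshold (log2), and the cause is the higher threshold or the other choice of probe sets. With tissue-restricted genes they were Myh11 -0.080, Cldn3 -0.19, Wap -0.59, Ltf -0.72, Wnt10b -0.11, Wnt10a -0.31, Msx2 -0.30, Sp5 -0.62, Snai1 -0.11, Krt1 -0.66, Krt6a -0.84, Shh -0.56, Egfl7 -0.024, Csf1r -0.84, Fcer1g -0.026, Epor -0.56, Tubb3 -0.27, Myod1 -0.24, Wnt3 -0.41, Hoxa7 -0.20, Itga2b -0.23, Fgf1 -0.62, Fgf4 -0.75, Fgf7 -0.79, Dsc3 -0.016 and Hnf4a -0.10. With the antigenomic threshold they were Myh11 -0.15, Cldn3 -0.26, Wap -0.65, Ltf -0.78, Wnt10b -0.17, Wnt10a -0.37, Msx2 -0.37, Sp5 -0.68, Snai1 -0.18, Krt1 -0.73, Krt6a -0.90, Shh -0.62, Egfl7 -0.089, Csf1r -0.91, Fcer1g -0.092, Epor -0.62, Pmel -0.050, Tubb3 -0.33, Myod1 -0.31, Wnt3 -0.47, Hoxa7 -0.26, Itga2b -0.29, Fgf1 -0.68, Fgf4 -0.82, Fgf7 -0.86, Dsc3 -0.082 and Hnf4a -0.17. With the mean of a gene's probe sets they were Csn2 -0.36, Msx2 -0.28, Fgf4 -0.35 and Hnf4a -0.090. Without cross-hybridising probe sets they were Top2a -0.083, Sry -0.28, Krt6a -0.88, Myef2 -1.70 and Dsc3 -0.24.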

Other observations

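Lists of further gene families were chosen after seeing the data and put through the same test (8 lists, adjusted over the 8). Basement membrane genes were above background in 15 of 16 cases (93.8%; exact Fisher adjusted p = 0.0128). They included the collagen IV chain genes Col4a1 (11.38 ± 0.17, SD, n = 3) and Col4a2 (9.84 ± 0.58), the laminin chain genes Lama1 (9.75 ± 0.14), Lama3 (10.09 ± 0.33) and Lamc1 (9.68 ± 0.04), the nidogen gene Nid1 (10.02 ± 0.18), and Fras1 (10.14 ± 0.53), a gene of the epidermal basement membrane. Genes of the Hedgehog pathway were above background in 11 of 13 cases (exact Fisher adjusted p = 0.157), with Smo at 11.16 ± 0.09, Gli2 at 9.64 ± 0.12, Gli3 at 8.18 ± 0.36, the receptor and target gene Ptch1 at 7.52 ± 0.44 and the target gene Gli1 at 7.02 ± 0.08.

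None of the other 6 lists passed. Klf genes reached 11 of 14 (exact Fisher adjusted p = 0.157), with Klf6 at 11.29 ± 0.25 and Klf4 at 10.06 ± 0.10 (SD, n = 3). Ephrins and Eph receptors and the semaphorins each reached 15 of 20 (0.157), for example Efna5 (10.25 ± 0.09), Epha4 (9.65 ± 0.03), Sema5a (11.13 ± 0.13) and Sema3c (9.71 ± 0.09). The Bmp list reached 11 of 17 (0.476), with Bmp2 at 9.48 ± 0.32, Bmp7 at 9.13 ± 0.42 and Bmp4 at 7.68 ± 0.35. Its members above background included Bmp1 and Bmp2k, which encode a protease and a kinase and not ligands. Sox genes reached 8 of 19 (0.294), for example Sox11 (10.68 ± 0.59), and T-box genes 5 of 15 (0.157), among them Tbx3 (9.90 ± 0.21), Tbx15 (7.82 ± 0.06) and Tbx5 (7.69 ± 0.22). The Sox genes above background were lower on replicate 2 than random lists matched on level (-0.37), outside the central 99.8%. These genes were chosen after their values were seen.

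The tests that follow were chosen after seeing the data. Replicates 1 and 2 resembled each other far more than either resembled replicate 3. A difference in the distribution of values alone does not account for the pattern. After joint quantile normalization of the probe set values, the SD of differences to replicate 3 was still 3.09 times that between replicates 1 and 2. That normalization cannot undo a separate background correction or summary of probes, so separate processing of replicate 3 stays open. A single cDNA library hybridised as replicates 1 and 2 stays open, and shifts of gene lists cannot decide it. In replicate 2 minus replicate 1, 6 of 24 lists lay outside the central range of matched random lists. They included the stress (0.45, log2), p63 target (0.29) and Hox genes (-0.36). The other lists lay inside that range. The noise between hybridisations of the same library was not measured, so shifts of this size cannot be told from it. A separate batch or number of sorted cells for replicate 3 stays open too, since the labels tie neither to an array. Of 23 antigenomic controls, 22 differed more on replicate 3. The replicate 3 difference was 0.23 at 3 G and C bases, -0.50 at 24 and 0.14 at 25. At 24 the values were 6.80, 6.82 and 6.31, while the array medians were 6.25, 6.25 and 6.52. A rescaling that keeps the order of values would not produce this, and separate background correction was not tested. A difference between the litters themselves was not tested.

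Mesenchymal genes such as Col1a1, Col3a1 and Dcn were above background in cells sorted for high CD49f, a gate that should remove dermal fibroblasts. Nonspecific hybridisation is argued against, since the median mesenchyme gene lay 2.61 (log2) above the brightest antigenomic control and 11 of 13 were above it. Dermal mesenchymal cells or their RNA in the sorted fraction may be a source and stays open: the median of mesenchyme genes minus that of junction genes was -0.32 for replicate 2 minus 1 and -1.08 for replicate 3 minus the others, but neither list lay outside the central 99.8% of random lists in either comparison, and each litter was measured once. Members stood at 12.99 ± 0.15 (Col1a1), 12.76 ± 0.13 (Col3a1) and 11.43 ± 0.07 (Dcn, SD, n = 3), whereas Pdgfra (4.89 ± 0.55) was not above background, and 1 gene of the list, Twist2, also stood on the list of transition genes. Expression by the mammary cells was not tested.

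Sry gave a signal in pools of female embryos (8.09 ± 0.04, SD, n = 3). Male embryos in the pools are argued against, since 0 of 5 other Y-linked genes were above background and each of their means lay below the threshold. Nonspecific hybridisation of the Sry probe set may account for it and stays open. The 2 probe sets of Sry disagreed, at 1.99 and -0.43 (log2) relative to the threshold. The higher one is marked as able to cross-hybridise, and without such probe sets Sry lay at -0.28. By the same test 11 of 44 genes restricted to unrelated tissues were above background, but Sry lay 0.71 above the brightest antigenomic control. No other biological explanation was tested.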
